A study of Mus musculus with 12 samples.

How the data were processed

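MIN6 cells, a mouse insulinoma line that secretes insulin, were measured in 4 groups of 3 libraries each. Per the series' design text, cells stably carried a parental control vector named PLKO1 (control cells, titled shCONTROL in the labels) or a short hairpin RNA against Ddx3x (knockdown cells). Each cell line was treated for 24 h with the vehicle DMSO or with 200 µM cyclopiazonic acid (CPA), an inhibitor of the SERCA calcium pump of the endoplasmic reticulum (ER). Groups and replicate numbers were taken from the labels. Titles tag the knockdown construct as DDX3X1 in vehicle-treated and as DDX3X in CPA-treated libraries, while the sample descriptions and the column names of the deposited values use DDX3X1 for both. Whether the tags mark different hairpins is not stated. Per the series' design text, poly(A) RNA was sequenced as paired reads on an Illumina NovaSeq X Plus. Per the submitters' processing notes, CASAVA, HISAT2 and the mouse build mm10 were used, with no version or role stated. The tool that assigned reads to genes, the annotation release and the use of strand are not given in the sources used here.

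The authors deposited a table of FPKM (fragments per kilobase of gene length, divided by library size) for 54532 genes, with the gene length behind each value and coordinates on GRCm38 (mm10). FPKM multiplied by gene length was a whole multiple of a single step per library for 100% of the values above 0, within a tolerance of 0.05 of a step. The reads behind each value were recovered from these steps. They totalled 26670171 to 33666742 in 10 libraries, 87055220 in replicate 2 and 184618155 in replicate 3 of CPA-treated knockdown cells. A single read in a gene of 1 kb was worth 0.00512 to 0.0475 FPKM, so low values were measured most precisely in those deeper libraries. The recovered total stood at 0.943 to 1.27 times the denominator the authors used, so their FPKM were not shares of the listed genes' reads.

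Where FPKM is divided by total reads, a fall of very abundant transcripts raises all others. Ins1 and Ins2, the insulin genes, took 4.36 to 5.67% of reads in vehicle-treated and 1.50 to 1.85% in CPA-treated control cells. Each library was therefore divided by its median ratio to the geometric mean library over the 11110 genes above 1 FPKM in all 12 libraries. This gave factors of 0.986 to 1.03, so the deposited values needed little further scaling. FPKM as deposited is thus an alternative close to the main setting. Scaled values are called scaled FPKM. Genes with at least 1 FPKM in at least 3 libraries were tested, 13582 in all.

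Differences were tested on log2(scaled FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (linear model of the 4 groups over all 12 libraries, empirical Bayes with a mean-variance trend, 3.44 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over the genes of a comparison, and genes under 0.05 were called. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. The 4 simple comparisons, the difference between both CPA effects (interaction) and the CPA effect averaged over both cell lines were fitted. The interaction is the CPA effect in knockdown cells minus that in control cells. Ddx3x itself was also compared by exact two-sided permutation tests. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

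Of 27 gene lists written from general knowledge, the 26 with measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Every list test was repeated with a correlation estimated from the residuals. Genes named in the text were Ddx3x, 15 core genes (Ddx3y and genes of the unfolded protein response and beta cell function), the 8 largest rises and the 8 largest falls of each comparison, and up to 4 members with the largest change per list. Slc2a2, a core gene, reached at most 0.84 FPKM and was not tested. Largest rises and falls were taken among called protein-coding genes with a mean of at least 5 scaled FPKM whose groups did not overlap (no such demand for the interaction). The groups, tests, gene lists, naming rule and most alternatives were set before the data were examined. Those alternatives were FPKM as deposited, quantile normalization, scaling to the sum of FPKM without the 20 most abundant genes, pseudocounts of 0.1 and 1, other filters on low values, fits on the 2 compared groups alone, no mean-variance trend, the replicate number as a block, a 2-fold threshold and leaving out each library. A sum of FPKM, unlike a sum of reads, gives short genes more weight. A count model (limma-voom) on the recovered reads, thinning of all libraries to the smallest total, removal of the trend on gene length, the overlap and list values without replicate 1 of CPA-treated knockdown cells and 8 further gene groups were added after the data had been seen.

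The steps were tested on simulated data built from the real means and spreads. For each comparison, 67 genes were changed 2-fold, and 13219 to 13238 genes were tested in all. Of the 67, 79.1% were recovered for the CPA effect in control cells and 73.1% for that in knockdown cells. For the knockdown effect, 77.6% were recovered in vehicle and 80.6% in CPA, and for the interaction 53.7%. Of 67 genes changed 1.5-fold, 13.4% were recovered for the interaction and 43.3% to 47.8% for the simple comparisons. Far fewer genes were changed than were called in the real simple comparisons, so recovery there may differ. No column of the table was left out. Genes that share reads with close copies, such as Ins1 and Ins2, the Rhox2 genes, Gm773, Ceacam10, histone cluster genes and ribosomal protein genes, have uncertain values, because the treatment of shared reads is not given in the sources used here.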

Results

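RNA was sequenced from MIN6 cells, a mouse insulinoma line used as a model of the pancreatic beta cell, to ask how loss of Ddx3x alters the transcriptome at rest and under ER stress. Ddx3x encodes a DEAD-box RNA helicase with roles in translation initiation. Control cells with a parental control vector and knockdown cells with a short hairpin RNA against Ddx3x received vehicle or 200 µM CPA for 24 h. CPA empties the calcium store of the ER and so disturbs protein folding there. Each of the 4 groups held 3 libraries. Depth came to 26670171 to 33666742 recovered reads in 10 libraries, and to 87055220 and 184618155 in replicates 2 and 3 of CPA-treated knockdown cells. Between 12491 and 12791 genes per library reached 1 FPKM. The leading principal component held 43.2% of the variance and parted the cell lines, and the next held 28.1% and parted the treatments. Replicates of a group correlated at Pearson's r of 0.974 to 0.988 across genes, which are not independent replicates. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

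Ddx3x (ENSMUSG00000000787, GRCm38 chromosome X, 13280970 to 13294052, plus strand) was lower in every knockdown library than in every control library of the same treatment. In vehicle, Ddx3x stood at 199, 295 and 213 scaled FPKM in control libraries and at 107, 107 and 85.4 in knockdown libraries. In CPA, it stood at 159, 157 and 170 in control libraries and at 82.8, 65.7 and 58.8 in knockdown libraries. Group means were 235 ± 52 against 99.8 ± 12.4 scaled FPKM in vehicle and 162 ± 7.3 against 69.1 ± 12.4 in CPA (SD, n = 3 each, exact permutation p = 0.1 in each treatment, the smallest that 3 against 3 libraries allow). Knockdown means were thus 57.6% and 57.4% lower. With labels permuted within treatment, 6 against 6 libraries gave an exact two-sided p of 0.005 over 400 arrangements. The limma fit put the Ddx3x change at log2 -1.22 (SE 0.165, adjusted p = 0.00021) in vehicle and -1.24 (SE 0.165, adjusted p = 0.000243) in CPA. CPA lowered Ddx3x 1.43-fold in control cells (adjusted p = 0.0304), a call that ended under quantile normalization (adjusted p = 0.486), without the 20 most abundant genes (0.154), without replicate 2 of vehicle-treated control cells (0.105) and without replicate 1, 2 or 3 of CPA-treated control cells (0.0754, 0.0821 and 0.057). In knockdown cells Ddx3x differed by log2 -0.53 under CPA (adjusted p = 0.0557). Ddx3y, the Y-linked relative of Ddx3x, was listed at 0 in all 12 libraries.

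**Figure D1:**
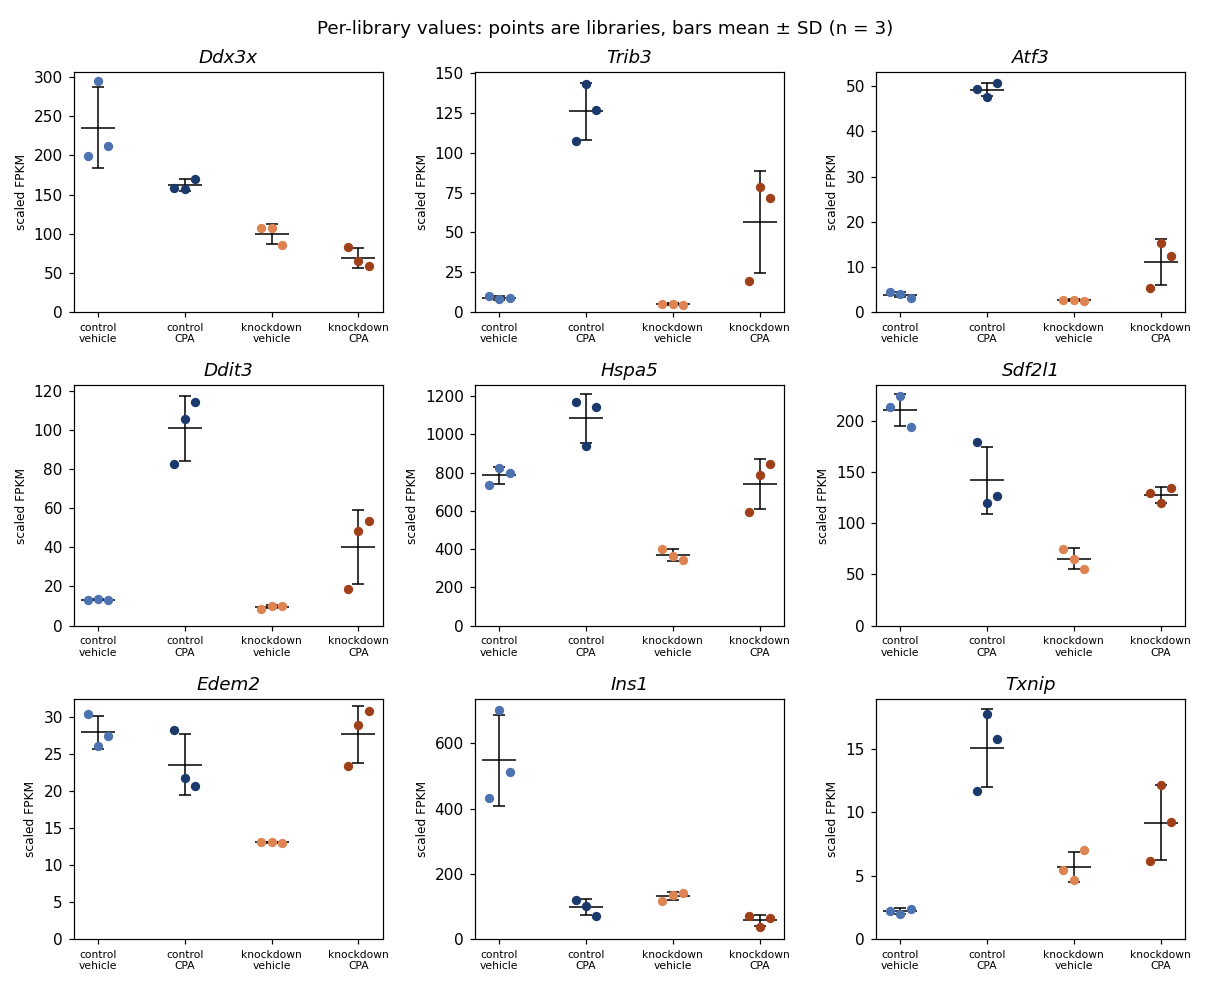
Scaled FPKM of 9 genes in the 4 groups of MIN6 libraries. Each point is a library, and bars mark the mean ± SD (n = 3): Ddx3x averaged 235, 162, 99.8 and 69.1 in vehicle-treated control, CPA-treated control, vehicle-treated knockdown and CPA-treated knockdown cells, and Trib3 averaged 9, 126, 5 and 56.5.

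In control cells, CPA raised genes of the PERK-ATF4-CHOP branch of the unfolded protein response and lowered insulin and other beta cell transcripts. Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032, minus strand), a pseudokinase induced through ATF4 and CHOP, rose 13.3-fold from 9 ± 1.15 to 126 ± 17.9 scaled FPKM (SD, n = 3 each, log2 3.73, SE 0.392, adjusted p = 0.000108). Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039, minus strand), a stress-induced transcription factor, rose 11.5-fold from 3.85 ± 0.617 to 49.3 ± 1.5 scaled FPKM (adjusted p = 4.64e-05). Ins1 (ENSMUSG00000035804, chromosome 19, 52264323 to 52265456, plus strand) fell 5.6-fold, from 549 ± 139 to 97.9 ± 24.9 scaled FPKM (log2 -2.48, SE 0.258, adjusted p = 0.000106). The widest fall among abundant protein-coding genes was that of C1qa, a complement subunit gene, at 15.6-fold, from 53.2 ± 6.14 to 3.12 ± 1.44 scaled FPKM (adjusted p = 6.07e-05). Nnat, which encodes the ER-resident proteolipid neuronatin, fell 7.51-fold from 161 ± 23.3 to 21.3 ± 5.33 scaled FPKM. Txnip, a thioredoxin-binding gene of the glucose response, rose 5.68-fold from 2.2 ± 0.219 to 15 ± 3.07 scaled FPKM (adjusted p = 6.4e-05). Mafa, a transcription factor of the mature beta cell, fell 2.68-fold (adjusted p = 0.00437). Ins2, the more abundant insulin gene, fell 3.32-fold from 43000 ± 10200 to 12800 ± 1410 scaled FPKM (adjusted p = 0.00182), but its change was 0 (adjusted p = 1) under quantile normalization, where its rank by FPKM was 2 in all 6 control libraries. Atf4 rose 1.75-fold and Herpud1, an ER-associated degradation gene, 2.03-fold (adjusted p = 0.0084 and 0.00234). Hspa5, which encodes the ER chaperone BiP, rose 1.38-fold (adjusted p = 0.0349), a call that ended without replicate 1 or 3 of vehicle-treated (adjusted p = 0.0973 and 0.0691) or of CPA-treated control cells (0.109 and 0.106). Xbp1 stood at 182 and 160 scaled FPKM (log2 -0.19, adjusted p = 0.0985) and Dnajb9, an ER co-chaperone gene, at 150 and 143 (log2 -0.06, adjusted p = 0.837). In this comparison 4868 genes were called, 2459 higher and 2409 lower, and 735 of them moved at least 2-fold. Scaling to the sum of FPKM without the 20 most abundant genes moved the median log2 of all genes from -0.013 to 0.221. It gave 4861 higher and 1014 lower, so directions of small changes are relative to the median gene.

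Of 30 measured PERK-ATF4-CHOP targets, 28 rose in CPA-treated control cells (29 rose and 1 fell adjusted over the list alone), with a median log2 of 1.51 and an adjusted p of 1.88e-15 (adjusted p = 0.413 with an estimated correlation). Among them were Trib3, Cth, the cystathionine gamma-lyase gene (9.76-fold), Ppp1r15a, which encodes the phosphatase subunit GADD34 (7.41-fold, 9.21 ± 0.988 to 71.4 ± 7.56 scaled FPKM), and Ddit3, which encodes CHOP (7.36-fold, 13.1 ± 0.238 to 101 ± 16.5). Cytosolic aminoacyl-tRNA synthetases rose in 14 of 20 cases (14 adjusted over the list alone), such as Lars 2.24-fold and Nars 2.19-fold. A median of 0.79 (log2) gave an adjusted p of 7.77e-06, or adjusted p = 0.413 with an estimated correlation. Cholesterol synthesis and uptake genes rose in 21 of 25 cases (23 adjusted over the list alone). With 0.82 as median log2, the list had an adjusted p of 6.79e-12 (adjusted p = 0.413 with an estimated correlation). Hmgcs1, which makes HMG-CoA, rose 4.05-fold and Insig1, an ER sensor protein gene of sterol control, rose 2.98-fold. Interferon-stimulated genes rose in 11 of 18 cases (11 adjusted over the list alone), among them the chemokine gene Cxcl10 (5.05-fold) and the antiviral gene Rsad2 (2.73-fold). At 0.44, the list's median log2 had an adjusted p of 0.00109 (adjusted p = 0.413 with an estimated correlation). Between 5 and 11 of them were called when each library was left out in turn.

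Genes of the ATF6 and IRE1 branches of the unfolded protein response moved in both directions in control cells. Of 22 measured ATF6-linked ER chaperone and ERAD genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone). Their median log2 was -0.03 and their mean 0.02, with an adjusted p of 0.799 (adjusted p = 0.933 with an estimated correlation), and the median was 0.173 under quantile normalization (adjusted p = 0.0238). Of 28 IRE1-XBP1 targets, 1 rose and 8 fell (1 and 8 adjusted over the list alone). Their median log2 of -0.21 had an adjusted p of 0.00275 (adjusted p = 0.506 with an estimated correlation). That median turned to 0.007 under quantile normalization, where the call ended (adjusted p = 0.555). Without the 20 most abundant genes it turned to 0.049, while camera still gave a lower direction (adjusted p = 0.023). Copb2, a coatomer gene, fell 1.89-fold, and Sec61b, a gene of the translocon, fell 1.66-fold. Beta cell identity and function genes fell in 25 of 39 cases (25 fell and 1 rose adjusted over the list alone). A median of -0.57 (log2) gave an adjusted p of 7.59e-09, or adjusted p = 0.413 with an estimated correlation. Nuclear-encoded subunits of oxidative phosphorylation fell in 54 of 74 cases and rose in 1 (55 and 1 adjusted over the list alone), with Uqcrh, a complex III subunit gene, 2.77-fold lower. With -0.51 as median log2, the list had an adjusted p of 2.14e-13 (adjusted p = 0.413 with an estimated correlation). Mitochondrially encoded genes fell in 6 of 13 cases (8 adjusted over the list alone, 0 to 9 with each library left out). At -0.855, their median log2 had an adjusted p of 0.00255 (adjusted p = 0.417 with an estimated correlation), which became 0.298 under quantile normalization. Mitochondrial transcripts took 4.78%, 6.74% and 5.14% of reads in vehicle-treated and 3.6%, 4.2% and 4.42% in CPA-treated control libraries, and the median was -0.572 without replicate 2 of vehicle-treated control cells, which held the highest share. Ribosomal protein genes fell in 25 of 82 cases and rose in 1 (20 and 1 adjusted over the list alone, 8 to 32 falls with each library left out). Their median log2 of -0.395 had an adjusted p of 3.75e-06 (adjusted p = 0.506 with an estimated correlation). Under quantile normalization it turned to 0.036 and the call ended (adjusted p = 0.481). Cell cycle genes fell in 19 of 33 cases and rose in 5 (19 and 5 adjusted over the list alone), but quantile normalization gave an adjusted p of 0.085. At -0.53, the list's median log2 had an adjusted p of 0.00263 (adjusted p = 0.506 with an estimated correlation). Ube2c, a mitotic ubiquitin-conjugating enzyme gene, changed by log2 -1.41 and Cdk1, the mitotic kinase gene, by -1.12. With each library left out in turn, 2 to 6 ATF6-linked genes, 5 to 10 IRE1-XBP1 targets and 12 to 19 cell cycle genes fell. No list call in any comparison held with an estimated correlation when all 12 libraries were used.

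In knockdown cells, CPA raised PERK-ATF4-CHOP targets, ER chaperone genes and sterol genes. Trib3 rose 8.83-fold from 5 ± 0.397 to 56.5 ± 32.1 scaled FPKM (SD, n = 3 each, log2 3.14, SE 0.392, adjusted p = 0.00183). Without replicate 1 of CPA-treated knockdown cells, which held 19.65 scaled FPKM against 78.4 and 71.3 in replicates 2 and 3, Trib3 rose 13.7-fold, near the 13.3-fold of control cells. Slc7a3, a cationic amino acid transporter gene, rose 7.74-fold from 4.3 ± 1.16 to 39.7 ± 20.3 scaled FPKM (adjusted p = 0.00119). Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, plus strand) rose 1.99-fold from 369 ± 30.4 to 742 ± 132 scaled FPKM (log2 0.99, SE 0.152, adjusted p = 0.00445). Hyou1, another ER chaperone gene, rose 2.28-fold from 68.9 ± 6.54 to 158 ± 17.7 scaled FPKM (adjusted p = 0.00119). Nnat fell 4.71-fold, from 189 ± 37.6 to 41.9 ± 17.9 scaled FPKM (adjusted p = 0.00232). Dnajb9 rose 2.05-fold (adjusted p = 0.0115), Ddit3 3.68-fold (adjusted p = 0.00548), Atf3 3.41-fold (adjusted p = 0.00466) and Atf4 2.12-fold (adjusted p = 0.00818). Ins1 fell 2.36-fold (adjusted p = 0.0143), a call that ended without replicate 2 of vehicle-treated (adjusted p = 0.0521) or of CPA-treated knockdown cells (adjusted p = 0.0541). Ins2 stood at 35700 ± 1610 and 24200 ± 6810 scaled FPKM (log2 -0.60, adjusted p = 0.219), Mafa at 373 ± 59.4 and 267 ± 140 (log2 -0.59, adjusted p = 0.209) and Txnip at 5.7 ± 1.19 and 9.18 ± 2.98 (log2 0.61, adjusted p = 0.0886).

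PERK-ATF4-CHOP targets rose in 28 of 30 cases in knockdown cells (29 adjusted over the list alone). A median of 1.33 (log2) gave an adjusted p of 3.41e-20, or adjusted p = 0.412 with an estimated correlation. ATF6-linked ER chaperone and ERAD genes rose in 15 of 22 cases (21 rose and 1 fell adjusted over the list alone). With 0.60 as median log2, the list had an adjusted p of 3.94e-13 (adjusted p = 0.412 with an estimated correlation). IRE1-XBP1 targets rose in 18 of 28 cases and fell in 1 (19 and 1 adjusted over the list alone). At 0.55, the list's median log2 had an adjusted p of 2.41e-09 (adjusted p = 0.412 with an estimated correlation). Derl3 of ER-associated degradation rose 2.33-fold, the calreticulin gene Calr 2.03-fold and Edem2, a lectin gene of glycoprotein degradation, 2.06-fold (13.1 ± 0.0763 to 27.7 ± 3.86 scaled FPKM). All 25 measured cholesterol genes rose (25 adjusted over the list alone), with Hmgcs1 4.7-fold, Lss, the lanosterol synthase gene, 3.62-fold and Insig1 3.51-fold higher. A median of 1.39 (log2) gave an adjusted p of 9.47e-30, or adjusted p = 0.248 with an estimated correlation. Cell cycle genes fell in 12 of 33 cases (19 adjusted over the list alone), among them Nusap1 of the mitotic spindle (log2 -1.05). With -0.43 as median log2, the list had an adjusted p of 9.39e-07 (adjusted p = 0.511 with an estimated correlation). Beta cell identity and function genes fell in 7 of 39 cases (7 adjusted over the list alone, 2 to 9 with each library left out). At -0.168, the list's median log2 had an adjusted p of 0.000114 (adjusted p = 0.412 with an estimated correlation), which became 0.173 under quantile normalization. Nuclear-encoded subunits of oxidative phosphorylation fell in 8 of 74 cases (21 adjusted over the list alone, 0 to 21 with each library left out, median -0.316, adjusted p = 3.01e-11, or adjusted p = 0.454 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 12 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone, 5 to 16 rises with each library left out, median 0.535, adjusted p = 1.28e-06, or adjusted p = 0.448 with an estimated correlation). Interferon-stimulated genes had a median log2 of 0.05 (adjusted p = 0.956), with 1 of 18 called lower (1 adjusted over the list alone). Without replicate 1 of CPA-treated knockdown cells, 20 cell cycle genes fell, with a median log2 of -0.629. Over all left-out libraries, 17 to 29 PERK-ATF4-CHOP targets and 11 to 19 IRE1-XBP1 targets rose and 4 to 20 cell cycle genes fell.

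In knockdown cells 1626 genes were called under CPA, 923 higher and 703 lower, against 791 and 908 with FPKM as deposited and 1272 and 429 without the 20 most abundant genes. The count became 726, 561 and 970 without replicate 1, 2 or 3 of vehicle-treated knockdown cells, 395 and 576 without replicate 2 or 3 of CPA-treated ones, 589 with no filter on low values and 621 when only these 6 libraries were fitted. Replicate 1 of CPA-treated knockdown cells stood apart from its group. Over the 735 genes that moved at least 2-fold in control cells, it lay at 0.422 of the way from the vehicle-treated knockdown libraries to replicates 2 and 3, while these lay at 1.06 and 0.774 when each was placed against the other. Its insulin transcripts took 4.13% of reads, against 2.42% and 3.42% in replicates 2 and 3. Without it, 2283 genes were called, and PERK-ATF4-CHOP targets and cholesterol genes each had an adjusted p of 0.0314 with an estimated correlation.

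Without CPA, knockdown cells had lower levels of the hormone genes Cck, Pdyn and Ins1 and of the ER genes Kdelr3 and Hspa5 than control cells. Cck (ENSMUSG00000032532, chromosome 9, 121489824 to 121495694, minus strand), the cholecystokinin gene, was 21-fold lower at 141 ± 139 against 2170 ± 304 scaled FPKM (SD, n = 3 each, log2 -4.39, SE 0.572, adjusted p = 0.000168). Pdyn (ENSMUSG00000027400, chromosome 2, 129686565 to 129699844, minus strand), the prodynorphin gene, was 29.5-fold lower at 23.2 ± 22 against 463 ± 61 scaled FPKM (adjusted p = 0.00104). With each library left out in turn, the log2 values ranged from -5.166 to -3.83 for Cck and from -5.682 to -3.915 for Pdyn. Kdelr3, a receptor that returns proteins to the ER, was 13.5-fold lower at 1.69 ± 0.576 against 28.5 ± 3.71 scaled FPKM (adjusted p = 4.89e-06). Hspa5 was 2.13-fold lower at 369 ± 30.4 against 786 ± 46.3 scaled FPKM (log2 -1.09, SE 0.152, adjusted p = 0.000259), and Ins1 4.1-fold lower at 131 ± 12 against 549 ± 139 (adjusted p = 0.000143). Among genes higher in knockdown cells, Rhox2h, a reproductive homeobox gene of the X chromosome with near-identical copies, stood at 87.3 ± 23.6 against 10 ± 4.08 scaled FPKM (8.54-fold, adjusted p = 1.34e-05). Insrr, an insulin receptor-related receptor gene, was 3.94-fold and Sytl4, a gene of insulin granule exocytosis, 3.45-fold higher. The detoxification genes Gstm1 and Nqo1 were 3.69-fold and 2.87-fold higher, and Txnip was 2.27-fold higher (adjusted p = 0.00165). Of 32 glutathione and thioredoxin enzyme genes, a group added after the data had been seen, 7 were higher and 8 lower. Ins2 differed by log2 -0.25 (adjusted p = 0.571) and by 0.836 (adjusted p = 0.000385) under quantile normalization, and Pdx1, a pancreatic transcription factor gene, by log2 -0.03 (adjusted p = 0.896). The comparison called 5010 genes, 2316 higher and 2694 lower, or 4507 and 1423 without the 20 most abundant genes, which moved the median log2 of all genes from -0.004 to 0.206.

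Of 28 IRE1-XBP1 targets, 27 were lower in vehicle-treated knockdown cells (27 adjusted over the list alone). At -0.86, the list's median log2 had an adjusted p of 1.21e-12 (adjusted p = 0.304 with an estimated correlation). ATF6-linked ER chaperone and ERAD genes were lower in 19 of 22 cases and higher in 1 (19 and 1 adjusted over the list alone). A median of -0.91 (log2) gave an adjusted p of 4.91e-08, or adjusted p = 0.304 with an estimated correlation. Sdf2l1, which partners BiP, was 3.23-fold lower, Mcfd2, a gene of ER export, 3.32-fold, Dnajc3 2.51-fold, and Ern1, which encodes the sensor IRE1, 2.35-fold lower. PERK-ATF4-CHOP targets were lower in 14 of 30 cases (17 lower and 2 higher adjusted over the list alone), as in Slc7a3 (5.13-fold) and the proline synthesis gene Pycr1 (5.08-fold). With -0.71 as median log2, the list had an adjusted p of 0.000477 (adjusted p = 0.733 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 51 of 82 cases (63 lower and 1 higher adjusted over the list alone), with Rpsa 2.53-fold and Rpl14 2.2-fold lower. At -0.56, the list's median log2 had an adjusted p of 2.89e-11 (adjusted p = 0.484 with an estimated correlation). Translation initiation factor genes were lower in 20 of 42 cases and higher in 2 (21 and 2 adjusted over the list alone). Their median log2 of -0.23 had an adjusted p of 0.000184 (adjusted p = 0.304 with an estimated correlation). Without the 20 most abundant genes it turned to 0.001, while camera still gave a lower direction (adjusted p = 0.0104). Interferon-stimulated genes were higher in 11 of 18 cases (14 adjusted over the list alone), among them the immunoproteasome genes Psmb8 (2.69-fold) and Psmb9 and the deconjugating enzyme gene Usp18 (2.29-fold). A median of 0.59 (log2) gave an adjusted p of 2.44e-05, or adjusted p = 0.304 with an estimated correlation. Psmb10, an immunoproteasome gene outside this list, was lower (log2 -0.453, adjusted p = 0.0126). Nuclear-encoded subunits of oxidative phosphorylation were lower in 24 of 74 cases (24 adjusted over the list alone, 8 to 26 with each library left out). Their median log2 of -0.306 had an adjusted p of 3.47e-06 (adjusted p = 0.582 with an estimated correlation), which became 0.203 under quantile normalization. Without replicate 1 of CPA-treated knockdown cells, which serves only the spread here, 24 PERK-ATF4-CHOP targets were lower (adjusted p of 2.23e-08, or adjusted p = 0.273 with an estimated correlation). Each library left out in turn gave 7 to 24 lower PERK-ATF4-CHOP targets, 32 to 58 lower ribosomal protein genes and 13 to 20 lower initiation factor genes.

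Endocrine identity genes moved in both directions in vehicle. Of 39 beta cell identity and function genes, 9 were higher and 8 lower in knockdown cells (10 and 8 adjusted over the list alone), with a median log2 of 0.08, a mean of -0.04 and an adjusted p of 0.742 (adjusted p = 0.898 with an estimated correlation). Iapp, the amylin gene, was 3.26-fold lower at 13900 ± 1260 against 46300 ± 12900 scaled FPKM, and Chgb, a granin gene of secretory granules, 4.25-fold lower. Markers of other islet endocrine cells were lower in 7 of 8 cases and higher in 1 (7 and 1 adjusted over the list alone), with the somatostatin gene Sst 20.3-fold lower, at 12.9 ± 4.11 scaled FPKM in control cells. With -1.52 as median log2, the list had an adjusted p of 0.00384 (adjusted p = 0.304 with an estimated correlation). Genes disallowed in mature beta cells or typical of progenitors were lower in 6 of 10 cases (6 adjusted over the list alone), with Oat, the ornithine aminotransferase gene, 4.82-fold lower. At -0.67, the list's median log2 had an adjusted p of 0.0218 (adjusted p = 0.304 with an estimated correlation). Exocrine and duct markers were lower in 4 of 5 measured cases (4 adjusted over the list alone). A median of -0.88 (log2) gave an adjusted p of 0.0243, or adjusted p = 0.304 with an estimated correlation. Between 2 and 4 of these were called with each library left out, and the beta cell median then ranged from -0.005 to 0.116. Of 20 fibroblast, endothelial and immune markers, 0 reached the level needed for testing.

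Under CPA, knockdown cells held lower levels of the stress response genes Atf3, Ddit3 and Ppp1r15a than control cells and higher levels of 22 of 39 beta cell identity and function genes, while 5 of these were lower. Atf3 was 4.69-fold lower at 11 ± 5.07 against 49.3 ± 1.5 scaled FPKM (SD, n = 3 each, log2 -2.23, SE 0.274, adjusted p = 0.00015). Ddit3 was 2.72-fold lower at 40.1 ± 18.9 against 101 ± 16.5 scaled FPKM (adjusted p = 0.00351), and Ppp1r15a 4.25-fold lower (adjusted p = 0.000205). Mafa was 2.89-fold higher at 267 ± 140 against 86.1 ± 18.5 scaled FPKM (log2 1.53, SE 0.299, adjusted p = 0.00237). Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651106, plus strand), an epithelial adhesion gene, was 8.64-fold lower at 1.09 ± 0.345 against 13.1 ± 1.05 scaled FPKM (adjusted p = 7.37e-07). Ins1 was 1.73-fold lower at 57.1 ± 17.5 against 97.9 ± 24.9 scaled FPKM (adjusted p = 0.0316), a call that ended without replicate 1 or 2 of CPA-treated control cells (adjusted p = 0.113 and 0.0838) or replicate 2 of CPA-treated knockdown cells (0.107). Ins2 was 1.85-fold higher at 24200 ± 6810 against 12800 ± 1410 scaled FPKM (adjusted p = 0.0416). The Ins2 call ended with a pseudocount of 0.1 (adjusted p = 0.0581), without replicate 1 or 3 of vehicle-treated control cells (0.0557 and 0.0554), without replicate 1, 2 or 3 of CPA-treated control cells (0.0817, 0.0987 and 0.159), without replicate 1 or 2 of vehicle-treated knockdown cells (0.0509 and 0.052) and without replicate 1 or 3 of CPA-treated knockdown cells (0.168 and 0.0958). Pdyn, Cck and Kdelr3 were 15.8-fold, 10.2-fold and 9.31-fold lower, with log2 values for Pdyn of -4.481 to -3.03 over the libraries left out. Stmn2, a neuronal microtubule regulator gene, was 4.83-fold higher, the activin receptor gene Acvr1c 4.14-fold and the incretin receptor gene Gipr 2.91-fold higher. Atf4 stood at 293 ± 84.6 against 382 ± 19.4 scaled FPKM (log2 -0.43, adjusted p = 0.106), and Herpud1 at 103 ± 32.9 against 128 ± 3.64 (log2 -0.37, adjusted p = 0.151).

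PERK-ATF4-CHOP targets were lower in 23 of 30 cases and higher in 1 in CPA-treated knockdown cells (24 and 1 adjusted over the list alone). With -0.86 as median log2, the list had an adjusted p of 4.03e-07 (adjusted p = 0.67 with an estimated correlation). Aminoacyl-tRNA synthetases were lower in 16 of 20 cases (16 adjusted over the list alone). At -0.50, the list's median log2 had an adjusted p of 9.3e-06 (adjusted p = 0.499 with an estimated correlation). Beta cell identity and function genes were higher in 22 of 39 cases and lower in 5 (22 and 7 adjusted over the list alone). A median of 0.50 (log2) gave an adjusted p of 0.000228, or adjusted p = 0.499 with an estimated correlation. Cholesterol genes were higher in 16 of 25 cases (18 adjusted over the list alone), such as Stard4 of sterol transport (log2 1.16) and the sterol reductase gene Tm7sf2 (log2 1.23). With 0.55 as median log2, the list had an adjusted p of 1.19e-05 (adjusted p = 0.67 with an estimated correlation). Ribosomal protein genes were lower in 45 of 82 cases and higher in 1 (46 and 2 adjusted over the list alone). At -0.48, the list's median log2 had an adjusted p of 8.94e-09 (adjusted p = 0.67 with an estimated correlation). Translation initiation factor genes were lower in 23 of 42 cases and higher in 1 (23 and 1 adjusted over the list alone, 15 to 23 lower with each library left out). Their median log2 of -0.25 had an adjusted p of 4.53e-05 (adjusted p = 0.339 with an estimated correlation). ATF6-linked genes had a median log2 of -0.13 (adjusted p = 0.375) and IRE1-XBP1 targets of -0.10 (adjusted p = 0.322), and both medians turned positive under quantile normalization, to 0.059 and 0.008. The comparison called 5170 genes, 2477 higher and 2693 lower, or 2888 and 1854 without the 20 most abundant genes. Without replicate 1 of CPA-treated knockdown cells, which lay nearer to vehicle than its group, 3964 genes were called. In that fit 19 PERK-ATF4-CHOP targets were lower and the list's median log2 was -0.526, with a range from -1.047 to -0.526 over all left-out libraries. The medians of ATF6-linked genes and IRE1-XBP1 targets then ranged from -0.234 to -0.04 and from -0.18 to -0.047.

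**Figure D2:**
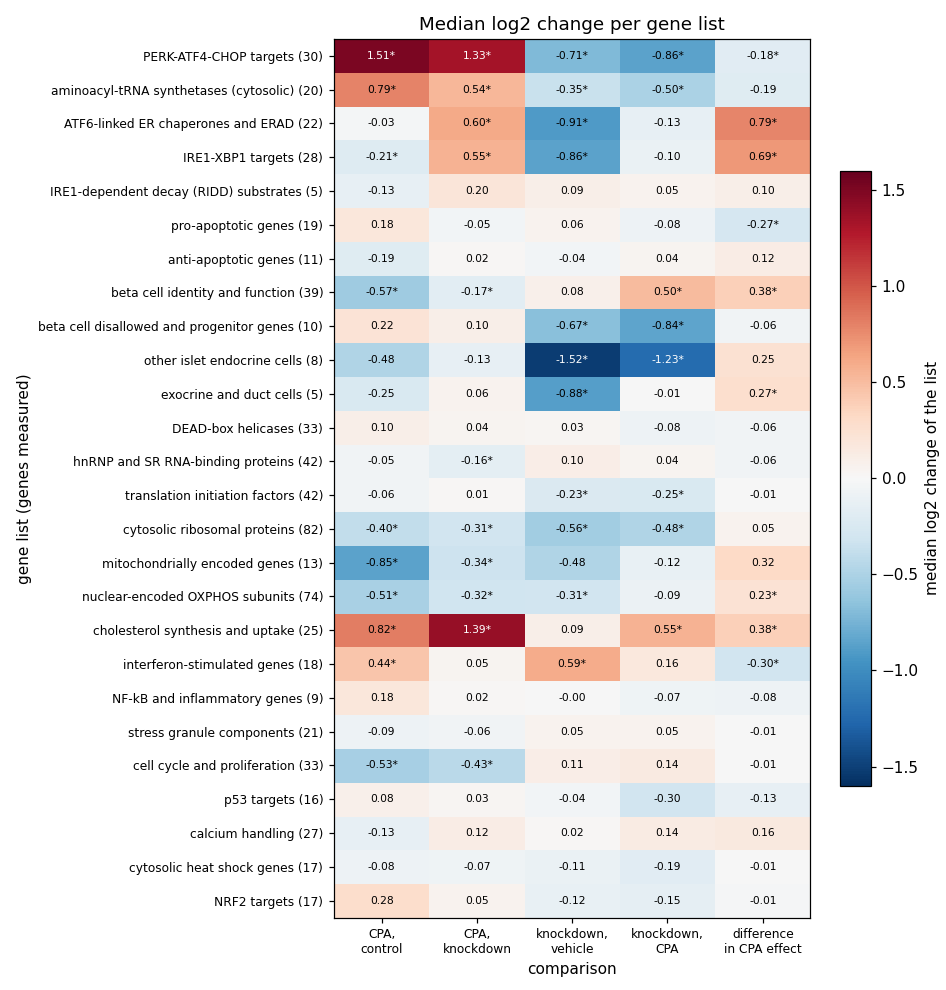
Median log2 change (color) of the measured genes of each list in 5 comparisons of MIN6 libraries (n = 3 per group), where asterisks mark camera calls at the preset correlation. ATF6-linked genes had medians of -0.03 under CPA in control cells (0.173 under quantile normalization) and 0.60 in knockdown cells, and IRE1-XBP1 targets had medians of -0.21 (0.007 under quantile normalization) and 0.55.

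The interaction asked which genes responded to CPA differently in knockdown and control cells. Among the named genes, the widest difference that kept its call without any single library was that of Bhlha15 (ENSMUSG00000052271, chromosome 5, 144190286 to 144194441, plus strand), which encodes MIST1, a transcription factor of secretory cells and a target of XBP1. Bhlha15 stood at 31.5 ± 1.57 scaled FPKM in vehicle and 15.8 ± 4.44 in CPA in control cells, and at 7.69 ± 0.714 and 20.5 ± 2.35 in knockdown cells (SD, n = 3 each, interaction log2 2.36, SE 0.222, adjusted p = 0.00387). Sdf2l1 (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383, minus strand) stood at 211 ± 15.4 and 142 ± 32.7 scaled FPKM in control cells and at 65.3 ± 10.1 and 128 ± 7.8 in knockdown cells (interaction log2 1.57, SE 0.22, adjusted p = 0.00861). Edem2 stood at 28 ± 2.22 and 23.6 ± 4.12 in control cells and at 13.1 ± 0.0763 and 27.7 ± 3.86 in knockdown cells (interaction log2 1.3, adjusted p = 0.00808). Hapln1, a matrix link protein gene, Kcnk16, a beta cell potassium channel gene, and Amigo3, an adhesion molecule gene, had interaction log2 values of 1.78, 1.49 and 1.48 (adjusted p = 0.00739, 0.0147 and 0.00739). Plk2, a stress-responsive kinase gene, had a smaller response in knockdown cells, at 0.944 and 3.24 scaled FPKM in control and 1.21 and 1.32 in knockdown cells (interaction log2 -1.29, adjusted p = 0.0088). Txnip also had a smaller response in knockdown cells (interaction log2 -1.89, adjusted p = 0.0154, or 0.0513 without replicate 3 of CPA-treated control cells). Ins1 had an interaction log2 of 1.24 (adjusted p = 0.1), Hspa5 of 0.53 (adjusted p = 0.222), Ddit3 of -1.0 (adjusted p = 0.252), Trib3 of -0.59 (adjusted p = 0.64), Mafa of 0.83 (adjusted p = 0.34) and Ddx3x of -0.02 (adjusted p = 0.982). The Trib3 value turned to 0.046 (adjusted p = 0.937) without replicate 1 of CPA-treated knockdown cells.

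Gene lists were tested for a shared interaction. IRE1-XBP1 targets had higher CPA effects in knockdown cells in 13 of 28 cases (24 adjusted over the list alone). A median of 0.69 (interaction log2) gave an adjusted p of 4.35e-20, or adjusted p = 0.198 with an estimated correlation. ATF6-linked genes did so in 10 of 22 cases (18 higher and 1 lower adjusted over the list alone). With 0.79 as median log2, the list had an adjusted p of 3.89e-11 (adjusted p = 0.23 with an estimated correlation). Beta cell identity genes fell less in knockdown cells, with medians of -0.168 against -0.572, and 3 of 39 had interaction calls toward a higher CPA effect (7 adjusted over the list alone). At 0.38, the list's median log2 had an adjusted p of 5.55e-06 (adjusted p = 0.23 with an estimated correlation). Cholesterol genes had higher CPA effects in 2 of 25 cases (2 adjusted over the list alone). A median of 0.38 (log2) gave an adjusted p of 3.32e-06, or adjusted p = 0.489 with an estimated correlation. Interferon-stimulated genes had lower CPA effects in 2 of 18 cases (3 adjusted over the list alone). With -0.30 as median log2, the list had an adjusted p of 1.83e-05 (adjusted p = 0.23 with an estimated correlation). Pro-apoptotic genes had lower CPA effects in 2 of 19 cases (3 adjusted over the list alone). At -0.27, the list's median log2 had an adjusted p of 0.00122 (adjusted p = 0.198 with an estimated correlation). Without replicate 1 of CPA-treated knockdown cells, the medians of the ATF6-linked genes and IRE1-XBP1 targets were 0.87 and 0.79. Cholesterol genes then had higher CPA effects in 7 of 25 cases (adjusted p of 3.76e-15, or adjusted p = 0.125 with an estimated correlation). Counts within lists were unsteady when each library was left out. They ranged from 1 to 13 for IRE1-XBP1 targets, 1 to 11 for ATF6-linked genes, 0 to 5 for beta cell identity genes and 0 to 7 for cholesterol genes. Interferon-stimulated genes gave 1 to 3 and pro-apoptotic genes 0 to 3. The interaction called 373 genes, 213 with a higher and 160 with a lower CPA effect in knockdown cells, or 72 and 179 without the 20 most abundant genes. The count became 168, 245 and 113 without replicate 1, 2 or 3 of vehicle-treated control cells, 78 and 43 without replicate 2 or 3 of CPA-treated control cells, 176 and 114 without replicate 1 or 3 of vehicle-treated and 109 without replicate 3 of CPA-treated knockdown cells, 246 under quantile normalization and 192 with no filter on low values.

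**Figure D3:**
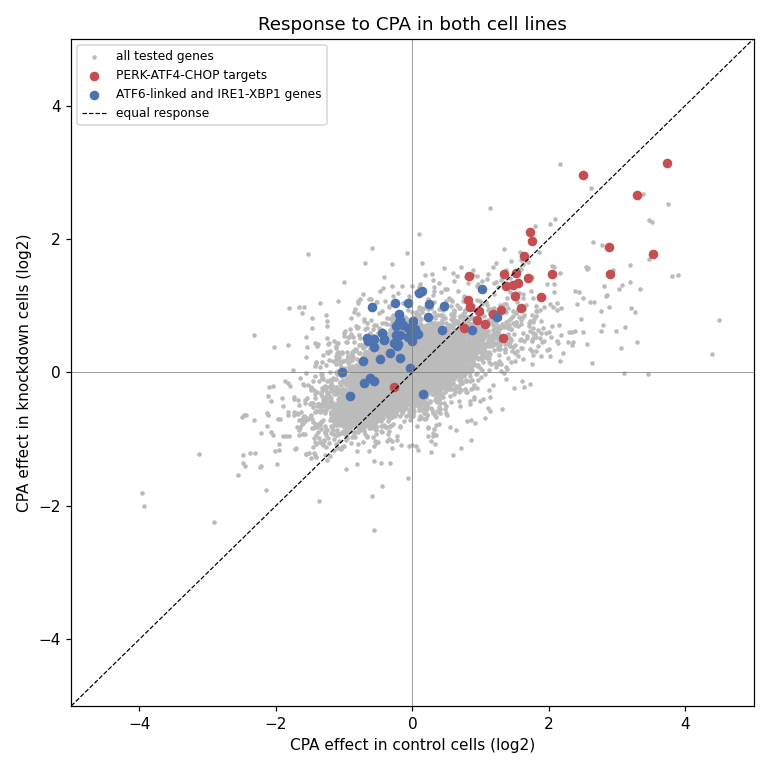
Log2 change under CPA in control cells (horizontal axis) and in knockdown cells (vertical axis), where each point is a gene tested in 3 libraries per group, grey for all genes, red for PERK-ATF4-CHOP targets and blue for ATF6-linked genes and IRE1-XBP1 targets. The dashed line marks equal responses, and blue points lie mostly above it, with median interaction log2 values of 0.79 for ATF6-linked genes and 0.69 for IRE1-XBP1 targets.

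The CPA responses of both cell lines were compared directly. Across genes, which are not independent replicates, they correlated at Pearson's r of 0.626 and Spearman's rho of 0.602, with no library in common. Both lines shared 580 called rises, where independent lists would share 167, and 543 called falls, where independent lists would share 125, while 28 genes called in both moved in opposite directions. Averaged over both lines, CPA changed 5693 genes, 2957 higher and 2736 lower, or 5518 and 1345 without the 20 most abundant genes. Of the 233 genes that rose at least 2-fold on average, 82.4% had a smaller response in knockdown cells, with medians of log2 1.75 in control and 0.975 in knockdown cells, and 48 of them had interaction calls toward a smaller response. Of the 140 that fell at least 2-fold, 91.4% had a smaller response in knockdown cells, with medians of -1.54 and -0.918, and 8 had interaction calls toward a smaller response. Without replicate 1 of CPA-treated knockdown cells, 74.6% and 75.3% responded less in knockdown cells, with medians of 1.63 against 1.18 and -1.42 against -1.06. In that fit, 45 rising genes had interaction calls toward a smaller and 7 toward a larger response, and 5 and 0 falling genes did. With all 12 libraries, 0 rising and 0 falling genes had calls toward a larger response. The knockdown effects in vehicle and in CPA correlated at Pearson's r of 0.709 and shared 1483 called rises and 1652 called falls, where independent lists would share 422 and 534.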

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

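The test of the secretory genes without each library in turn, thinning and removal of the gene length trend were chosen only after the results were seen. The results below drew attention because the CPA effect differed between knockdown and control cells by the interaction test.

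ATF6-linked genes and IRE1-XBP1 targets had median interaction log2 values of 0.79 and 0.69, with Bhlha15 at 2.36, Sdf2l1 at 1.57, Fkbp11 at 1.5, Edem2 at 1.3 and Sec24d at 1.04. Many secretory pathway genes that were lower in knockdown cells in vehicle thus stood nearer to control levels under CPA. In knockdown cells, 15 of 22 ATF6-linked genes and 18 of 28 IRE1-XBP1 targets rose, and 1 of the latter fell. In control cells 6 and 8 of them fell and 4 and 1 rose, so control levels moved too. Kdelr3 stayed lower in CPA-treated knockdown cells. Read sampling at unequal depth was argued against. The median of 0.717 over the 50 genes of both lists stayed at 0.706 or more in 20 draws thinned to equal depth. Thinning keeps the expected values, so it cannot test a difference in how the deeper libraries were made or run. A single library as the cause was argued against by a lowest median of 0.613 when each library was left out, and a gene length trend by 0.717 after its removal. A biological hypothesis, which no measurement here tests, is that Ddx3x loss may lower the resting activity of the IRE1 and ATF6 branches, whose lists differed by -0.86 and -0.91 in vehicle, and that ER stress offsets this, as the lists differed by -0.10 and -0.13 in CPA (0.008 and 0.059 under quantile normalization). It stays open whether the short hairpin or another difference between the 2 cell lines lies behind it. The labels name no rescue. Sample descriptions give vehicle-treated and CPA-treated knockdown libraries the same construct tag, while titles give them different ones, and no label states that the hairpin was the same. Xbp1 splicing, which would test IRE1 activity, cannot be read from these gene values.

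Further genes with a higher CPA effect in knockdown cells were C1qtnf1 (2.33), C1qa (2.15), Hapln1 (1.78), Kcnk16 (1.49) and Amigo3 (1.48). Genes with a lower CPA effect there were Gclc (-0.67), Trp53inp1 (-1.22), Plk2 (-1.29), Hist1h1b (-1.74), Retsat (-1.74), Atf3 (-1.76), Txnip (-1.89), Cdsn (-2.08), Lhfpl2 (-2.24), Avil (-2.36) and Hist1h2bj (-3.47), in log2 units. Of the 32 named genes called in the interaction, 8 kept the call without any single library, namely Bhlha15, Sdf2l1, Edem2, Hapln1, Kcnk16, Amigo3, Plk2 and Cxcl10, and 24 lost it without at least 1 library. Among these, Sec24d lost it without replicate 3 of CPA-treated control cells (adjusted p = 0.0513), and C1qtnf1 without replicate 2 or 3 of that group (0.0531 and 0.0555). Other calls ended in most of the 12 fits without a single library. Cdsn lost its call in 11 fits (adjusted p up to 0.124), and Atf3, Fkbp11 and Sst in 10 (up to 0.102, 0.112 and 0.111). C1qa lost its call in 9 fits (up to 0.103) and Trp53inp1 in 8 (up to 0.105).

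List medians of the interaction were 0.38 for beta cell identity and function, 0.38 for cholesterol synthesis and uptake, 0.27 for exocrine and duct markers, 0.23 for nuclear-encoded subunits of oxidative phosphorylation (adjusted p = 0.0856 under quantile normalization), -0.27 for pro-apoptotic genes and -0.30 for interferon-stimulated genes. The median for PERK-ATF4-CHOP targets was -0.18 (adjusted p = 0.0285), but 0.107 (adjusted p = 0.382) without replicate 1 of CPA-treated knockdown cells. Its adjusted p was 0.13, 0.0595, 0.0623 and 0.0935 without replicate 2 of vehicle-treated control, 3 of CPA-treated control, 1 and 2 of vehicle-treated knockdown cells. The exocrine and duct list had an adjusted p of 0.0644, 0.0595 and 0.0713 without replicate 1 of vehicle-treated control, 3 of CPA-treated control and 2 of CPA-treated knockdown cells. With an estimated correlation, the adjusted p was 0.771 for PERK-ATF4-CHOP targets, 0.247 for exocrine and duct markers and 0.607 for nuclear-encoded subunits of oxidative phosphorylation.

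Other splits of the same libraries were counted. For each simple comparison 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts in fits of 2 groups were 4402 and 621 for CPA in control and knockdown cells and 4388 and 4661 for knockdown in vehicle and in CPA, and the highest of the other splits gave 0, 1, 0 and 0. For the averaged CPA effect, 1 of 100 splits, the real one, gave as many genes (5693, highest other 3178). The highest other split kept all 6 treatment labels of control cells in place, so it carried part of the CPA effect. Whether replicates were separate cultures is not given, so no exclusion of chance is drawn from this share. For the interaction, 4 of 100 splits gave as many (373, highest other 1524). The 3 splits with more genes kept the vehicle labels in place and exchanged 4 of the 6 CPA labels between the cell lines, up to the sign of the contrast. This points to a structure of the samples, the wide difference between the lines, which such exchanges carry into the contrast or the spread, so these splits say little about chance in the interaction.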

How the results depend on the processing

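The count model on recovered reads, thinning and removal of the length trend were chosen only after the results were seen. Over all alternatives, 131 counts of called genes stayed within 1.5 times and 23 moved further. Of gene values, 9887 kept direction and side of the threshold, 39 stayed uncalled but turned direction, 544 lost and 119 gained a call and 2 reversed. Of list values, 3041 kept both, 78 stayed uncalled but turned, 105 lost and 48 gained a call and 4 reversed. Reversed means that the direction changed and that the main fit, the alternative or both gave a call. A 2-fold threshold, stricter by construction, left 735 and 185 genes for CPA in control and knockdown cells, 834 and 884 for knockdown in vehicle and in CPA, 149 for the interaction and 373 for the averaged effect. For CPA in knockdown cells, no filter on low values gave 589 genes and a fit on the 2 groups alone 621, with fewer libraries behind the spread. For the interaction, quantile normalization gave 246 and no filter 192. Without the 20 most abundant genes, the CPA calls shared by both lines were 961 rises and 252 falls, and under quantile normalization 81% of responsive genes moved less in knockdown cells. Leaving out each library gave 3491 to 4950 and 395 to 2301 genes for CPA in control and knockdown cells, 3620 to 5233 and 3964 to 5494 for knockdown in vehicle and in CPA, 43 to 390 for the interaction and 4654 to 5828 for the averaged effect. Quantile normalization moved Ins2 to 0 (adjusted p = 1) for CPA in control cells, a lost call that was counted as reversed. For knockdown in vehicle, where the main fit gave no call, it turned Ins2 to 0.836 (adjusted p = 0.000385). Both came about because the rank of Ins2 was 2 in all control and 1 in all knockdown libraries. Quantile normalization also reversed the ATF6-linked list (0.173, adjusted p = 0.0238) and ribosomal protein genes (0.036, adjusted p = 0.481) for CPA in control cells, and ribosomal protein genes in the interaction (-0.152, adjusted p = 0.002). PERK-ATF4-CHOP targets in the interaction reversed to 0.107 (adjusted p = 0.382) without replicate 1 of CPA-treated knockdown cells, in a range from -0.36 over the libraries left out. For these lists, the moved overlaps and the filter, the cause was not tested. The count model called 4654, 2398, 4852, 5440, 369 and 5792 genes in the order above, and thinned libraries 4767, 1558, 4912, 5120, 351 and 5576. Depth limits genes near 0.0475 FPKM per read at 1 kb in the shallowest library.

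Replicate numbers are shared between groups, but same-numbered libraries deviated together in only 4 of 18 pairs (r over 0.1, range -0.358 to 0.296), and 5 of 12 libraries correlated best with their own number. Between vehicle and CPA, replicates 1, 2 and 3 gave r of 0.0665, 0.296 and 0.202 in knockdown cells and 0.111, -0.0271 and -0.0746 in control cells. Pairing within the knockdown line thus stays open. With the replicate block, 4664, 1323, 4889, 5005, 276 and 5516 genes were called in the same order, each within 1.5 times of the fit without it.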

Other observations

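The gene groups, the chromosome 9 segment and the label swap test described here were chosen only after the data had been seen. Histone cluster genes, whose replication-dependent transcripts mostly lack poly(A) tails, responded to CPA differently in the cell lines. Of 39 measured, 12 had a lower CPA effect in knockdown cells, with a median interaction log2 of -0.80 (adjusted p = 2.31e-13 over 8 added groups, or adjusted p = 0.24 with an estimated correlation), including Hist1h4m (-1.90), Hist1h1a (-1.86) and Hist1h2ac (-1.74). In control cells under CPA, 13 rose and 5 fell (median log2 0.20, adjusted p = 0.128), and in knockdown cells 11 fell (median -0.54, adjusted p = 1.28e-10, or adjusted p = 0.232 with an estimated correlation). These genes share reads with close copies, so single values are uncertain.

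One-carbon and serine synthesis genes rose under CPA in 8 of 14 cases in control cells (1 fell; median log2 0.79, adjusted p = 0.00869, or adjusted p = 0.377 with an estimated correlation) and in 10 of 14 in knockdown cells (median 0.86, adjusted p = 2.76e-06, or adjusted p = 0.232 with an estimated correlation). Shmt2, the mitochondrial serine hydroxymethyltransferase gene, changed by log2 1.54 and 1.34. The group shares Phgdh, Psph, Shmt2, Aldh1l2, Aldh18a1 and Pycr1 with the PERK-ATF4-CHOP list, so its rise is not separate from that list's. Neuropeptide and granule protein genes fell in 9 of 18 cases in CPA-treated control cells and rose in 1 (median -0.64, adjusted p = 0.00869, or adjusted p = 0.377 with an estimated correlation), with neurotensin (Nts) at log2 2.18 and Npy at -1.24. In vehicle, 8 of the 18 were lower in knockdown cells and 1 was higher (median -0.43, adjusted p = 0.018, or adjusted p = 0.521 with an estimated correlation), the latter being Npy (log2 1.04). These genes overlap the beta cell list, for example in Pcsk1, Pcsk2, Scg2, Chgb and Ptprn2. Proton pump (V-ATPase) subunit genes were lower in 7 of 16 cases in vehicle-treated knockdown cells (median -0.24, adjusted p = 0.00785, or adjusted p = 0.084 with an estimated correlation). Mitochondrial ribosomal protein genes were lower in 28 of 77 cases and higher in 1 in CPA-treated knockdown cells (median -0.24, adjusted p = 0.000352, or adjusted p = 0.44 with an estimated correlation).

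Replicate 1 of CPA-treated knockdown cells lay at 0.422 on the scale from vehicle (0) to the other CPA-treated knockdown libraries (1), while CPA-treated control libraries lay at 0.897 to 1.08 on that of their own line. The genes were chosen by their change in these control libraries, which favors control positions near 1. A swap of labels with a vehicle library was argued against, because the highest vehicle knockdown library lay at 0.107. Read sampling at low depth was argued against, because the position was 0.413 after thinning to equal depth. Thinning keeps the expected values, so it cannot test other differences between the deeper libraries and replicate 1. A mixture of treated and untreated material would place the library alike by rising and by falling genes. Rising genes placed it at 0.323 and falling genes at 0.527 on the linear scale. The difference was -0.205, with a 95% bootstrap interval over genes of -0.259 to -0.143. This interval lies away from equal positions, but genes are not independent replicates and a single library was placed, so a mixture stays open. No value in the labels tests whether that sample took up less CPA.

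The wide difference between the lines in vehicle could in part come from copy number. Windows of 10 Mb explained 1.63% of the variance of the knockdown fold changes, which argues against copy number as the whole cause. For CPA in control cells, a comparison within a single line, they explained 1.03%. Several windows were shifted in vehicle, such as chromosome 16 from 90 to 100 Mb (63 genes, median log2 0.381) and chromosome 18 from 60 to 70 Mb (46 genes, -0.318). Over chromosome 9 from 100 to 130 Mb, where Cck lies, 206 genes had a median log2 of -0.40 in vehicle (109 lower and 26 higher). In the CPA-treated libraries, which the vehicle comparison does not use, their median was -0.287 (interval -0.378 to -0.175), against 0.029 for the rest of the chromosome. These libraries come from the same 2 cell lines, whose knockdown effects in vehicle and in CPA correlated at Pearson's r of 0.709 across genes. A segment chosen as low in vehicle would thus tend to be low in CPA whatever the cause. Fewer copies of that segment in the knockdown line may contribute, and this stays open because the interval reaches past -0.2 and expression alone does not measure copies.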
